A study of Mus musculus with 10 samples.

How the data were processed

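RNA from 5 cell populations sorted by flow cytometry from C57BL/6 mice carrying a green fluorescent protein (GFP) reporter in the Rorc (γt) locus was measured on one-colour Agilent mouse arrays, with 2 arrays per population and 10 in all. Per the labels, CD3- lamina propria cells of the small intestine (SI) and splenocytes were freed with Collagenase VIII, 1000 cells of each subset were sorted and lysed, the lysates were thawed together, and RNA was amplified and labelled with Cy3 by the SuperAmp procedure. Each scanner file holds, per the file headers, the intensity of every spot as quantified by the authors with Agilent Feature Extraction, version 10.2.1.3 for replicate 1 and 10.5.1.1 for replicate 2. The processed signal in these deposited files is background-subtracted and detrended within an array and not normalised between arrays. The authors also deposited a matrix of log2 values, for which the submitters name R 2.7.0 and limma. Its columns follow the rank order of mean signal minus local background (rank correlation 1 on every array) and share nearly the same distribution, with medians of 6.10 to 6.13. The normalisation behind it is not stated. Each column correlated best with its own array (r 0.969 to 0.992, against at most 0.805 with any other array).

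On each array 1639 control spots were left out. The file of replicate 1 of the Spleen NKp46+GFP- cells had been saved again by a spreadsheet program: its values carry no more than 3 significant digits and 26 gene names were altered, so names were taken from the other files. That array also had 818 spots marked as outliers by the scanner software, against 84 to 163 on the others. These spots were left out, and 472 genes, among them the NK cell genes Gzma, Tbx21, Klra1 and Klrd1, therefore have a value on only 1 Spleen array. Probe names were brought to current symbols through accessions (24375 probes), symbols (6301) or synonyms (2426) of the supplied RefSeq pairs, and 8072 probes kept the name in the file. Probe positions are those printed in the files, on mouse build mm8.

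Values are log2 processed signal minus the log2 75th percentile of the array. Spots of the same probe were averaged. A probe was kept when well above background on both arrays of at least 1 group (31382 of 41174 probes), and the brightest probe stood for each gene, which left 22142 genes, 17359 of them with a symbol in the reference. All 10 arrays were fitted together with limma 3.58.1 in R 4.3.3 (data.table, version 1.17.8), with 5 group means, moderated by eBayes (5 residual and 2.15 prior degrees of freedom). Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes were called. Since 2 arrays per group limit precision, only large differences can be called: tested on simulated data, changes of 2, 4, 6 and 8 on the log2 scale were called in 0, 4, 18 and 32 of 50 genes, with 5 unchanged genes among 59 calls. The simulated noise was normal and independent between genes. It did not include signal present on 1 array of a group and absent on the other, so these counts do not cover such genes. A gene whose probe was not well above background in the lower group is given as at least so many fold different, measured against the lowest signal that was well above background. Where the lower group had such signal on 1 of 2 arrays, each array was set to the higher of that lowest signal and its own value, and the number of arrays is given.

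20 gene lists were written before the data were examined: cytotoxic effectors, NK cell receptors, NK maturation and circulation, type 1 programme, IL-17 and IL-22 axis, lymphoid tissue inducer programme, group 2 ILC programme, AHR and Notch pathways, gut homing and tissue retention, immediate early and stress response, interferon-stimulated genes, cell cycle, glycolysis, and markers of T cells, B and plasma cells, epithelium, myeloid cells, mast cells and basophils, stroma and endothelium, and erythroid cells and platelets. Of their 456 symbols 404 were tested. 13 genes stand on more than 1 list, such as Rora on the IL-17 and IL-22 and the lymphoid tissue inducer lists, Ccr7 on the NK maturation and the lymphoid tissue inducer lists, and Cma1 on the NK maturation and the mast cell lists. A list was tested with limma's camera at the preset correlation of 0.01, with adjustment over the 20 lists of a comparison. Camera with an estimated correlation, which allows the genes of a list to vary together, is given beside it. The preset test compared the moderated t of a list's genes, turned into z scores, with that of all other genes. It did not use ranks, so a few extreme genes can weigh on a list. The test with an estimated correlation used the values of genes measured on every array. It left out 570 genes with a missing array, among them Gzma, Tbx21, Klra1 and Klrd1. A call lost there need not stem from the correlation alone. A list's shift is the mean log2 difference of its genes minus that of all genes. List members were also counted after adjustment over the list alone.

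The comparisons, the tests and the rule for naming genes were also fixed before the data were examined. Ncr1 and Rorc, the genes behind the sort, are given first. For each comparison the rule takes the 6 largest log2 differences each way among called genes with separated arrays and signal in both groups, the 3 smallest adjusted p each way among called genes without signal in the lower group, and up to 4 members per list with the smallest p. Where fewer than 3 genes were called in a direction, the 3 with the smallest p are given and said not to have passed. Only genes with a symbol are named by it. Genes of the near-identical Klra, Gzm, immunoglobulin, H2 and Hbb families are open to cross-hybridisation.

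Replicate number coincides with the slide for the SI arrays, with the Feature Extraction version for all arrays, and the Spleen arrays sat on slides of their own. Between groups, deviations of equally numbered arrays from their group mean correlated weakly across genes (r 0.0131 to 0.111), and the consensus correlation of arrays on a slide was 0.052, so no block was used in the main model. Alternatives fixed beforehand were normexp background correction (offset 50), quantile normalisation, the authors' log2 values, no filter on background, the mean of all probes of a gene, the replicate number as a block, the slide as a random block, a fit of only the 4 arrays compared, and leaving out each array. Keeping the outlier-marked spots was added after the data had been seen. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.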

Results

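Transcripts of 5 populations of innate lymphoid cells from RORγt reporter mice were measured on 10 arrays, 2 per population. From the SI lamina propria came SI NKp46+GFP- cells, SI NKp46+GFPlow cells, SI NKp46+GFPhigh cells and SI NKp46-GFP+ cells, the last of which include adult lymphoid tissue inducer cells. Spleen NKp46+GFP- cells served as reference conventional natural killer (NK) cells. On each array 27024 to 35181 probe spots were well above background (62.3 to 81.1%), and none was saturated. In all 22142 genes were tested, of which about 1107 would have an unadjusted p under 0.05 by chance in a comparison. With 2 arrays per group the number of arrays limits precision, and the p-values measure the spread between these samples, which the labels do not state to come from separate animals. Values are log2 relative to the 75th percentile of the array, shown with the SD of 2 arrays. In 6 of 7 comparisons the median gene differed by more than 0.1 between the groups, and the differences are reported relative to the 75th percentile.

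In group means the genes behind the sort followed the gates. Ncr1, which encodes NKp46, was at 5.23 ± 0.55 in SI NKp46+GFP- cells, 3.40 ± 1.06 in SI NKp46+GFPlow cells, 4.27 ± 0.64 in SI NKp46+GFPhigh cells, -0.45 ± 1.16 in SI NKp46-GFP+ cells and 5.22 ± 0.62 in Spleen NKp46+GFP- cells. Rorc, which encodes RORγt, stood at 0.92 ± 1.06, 2.09 ± 0.59, 3.40 ± 0.06, 3.03 ± 0.46 and -5.42 ± 2.52 in the same order, so SI NKp46+GFP- cells held Rorc signal above that of spleen cells. In replicate 1 Rorc was alike in SI NKp46+GFP- and SI NKp46+GFPlow cells (1.67 in both). The Ncr1 probe lies at chr 7 3947661-3947720 and the Rorc probe at chr 3 94483091-94483150 on mm8. Across genes the 2 arrays of a group correlated at a mean r of 0.725 (0.691 to 0.747, 5 values), and arrays of different groups at 0.690 (0.604 to 0.781, 40 values). By correlation the closest groups were SI NKp46+GFP- and SI NKp46+GFPhigh cells (0.734) and the most distant Spleen NKp46+GFP- and SI NKp46+GFPlow cells (0.648). By the root mean square log2 difference of group means the closest were SI NKp46+GFPlow and SI NKp46-GFP+ cells (1.56) and the most distant Spleen NKp46+GFP- and SI NKp46+GFP- cells (2.00), so the order depends on the measure.

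**Figure D1:**
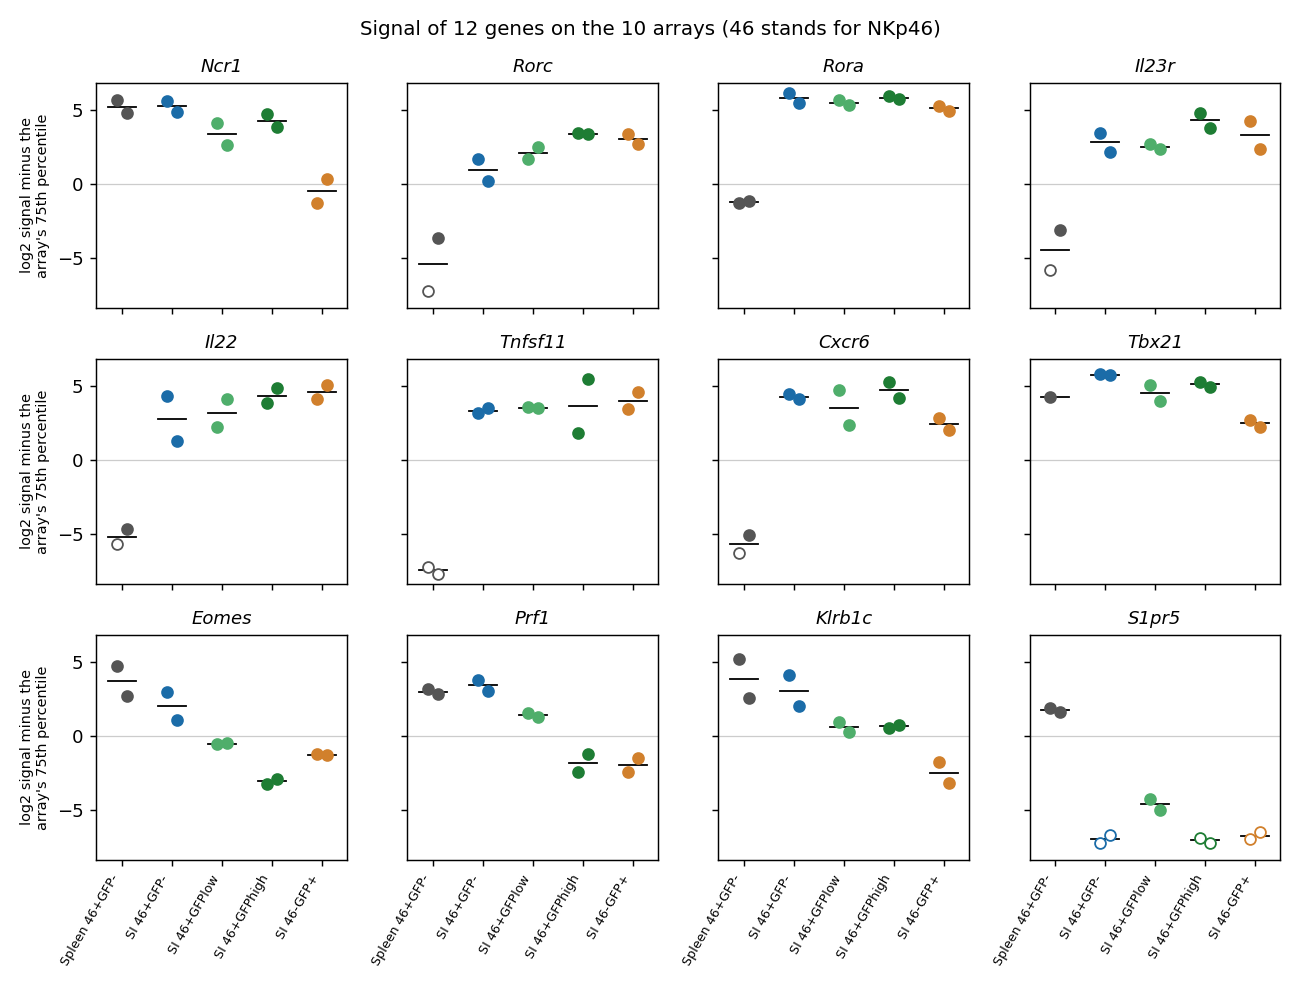
Log2 signal relative to the array 75th percentile (vertical axis) of 12 genes on each of the 10 arrays, grouped by population (horizontal axis); filled points are well above background, open points are not, and the black line is the group mean. Rora was at 5.79 in SI NKp46+GFP- cells and -1.18 in Spleen NKp46+GFP- cells, and Prf1 at 3.41 in SI NKp46+GFP- and -1.83 in SI NKp46+GFPhigh cells.

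How do SI NKp46+GFP- cells differ from Spleen NKp46+GFP- cells, which share their sort phenotype? The IL-17 and IL-22 and lymphoid tissue inducer lists (below, RORγt-linked lists) were higher in the gut cells. So were the lists of tissue residence and of the immediate early response, and genes of NK cell maturation and circulation were lower. With an estimated correlation none of these list calls held (adjusted p = 0.102 for the IL-17 and IL-22 axis and for immediate early genes, 0.14 for the lymphoid tissue inducer list, 0.0694 for gut homing and 0.413 for NK maturation). The chemokine receptor gene Cxcr6 was at least 654-fold higher, with signal on 1 of 2 spleen arrays, and Rora, which encodes a nuclear receptor of innate lymphoid cells, was higher by 6.97. S1pr5, whose receptor guides NK cells out of tissues, was at least 119-fold lower. Ncr1 was alike (difference 0.01, adjusted p = 0.996), and Rorc was at least 38.9-fold higher without passing (adjusted p = 0.133). The median gene was lower by 0.44 in the gut cells. Spleen arrays sat on slides of their own, so tissue and slide cannot be told apart here.

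By limma 43 genes were called, 36 higher and 7 lower in the gut cells, and 2329 had an unadjusted p under 0.05. The largest estimated increases with signal on at least 1 array of each group were those of Cxcr6 (adjusted p = 0.0185) and the transcriptional repressor gene Tgif1 (at least 501-fold, adjusted p = 0.0468), both with signal on 1 of 2 spleen arrays, the survival gene Bcl2l1 (8.03), Litaf (7.78), Serpinb1b (7.58; adjusted p = 0.0365 for the last 3) and Dgat1 (7.19; adjusted p = 0.011). Without signal in spleen, Rnf17 rose at least 1193-fold, the phosphatase gene Dusp4 at least 235-fold and Dhx40 at least 287-fold. Among genes that fell with S1pr5 (adjusted p = 0.00693) was Hdgfl3, at least 40.1-fold lower (adjusted p = 0.011). Both gut arrays lay beyond both spleen arrays for each of these genes.

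The 17 genes of the IL-17 and IL-22 axis shifted up by 3.06 (adjusted p = 2.45e-08, adjusted p = 0.102 with an estimated correlation), 13 of them higher, with shifts of 3.06 in replicate 1 and 3.07 in replicate 2. Of these, 1 passed over all genes and 3 when adjusted over the list alone: Rora, the cytokine gene Il22 (at least 202-fold higher, list-alone adjusted p = 0.00151) and the IL-23 receptor gene Il23r (at least 119-fold, 0.00151), both with signal on 1 of 2 spleen arrays, while Il2 (2.83) did not pass. The lymphoid tissue inducer list (31 genes, 1 of them, Rora, also on the former list) shifted up by 2.15 (adjusted p = 1.22e-05, adjusted p = 0.14 with an estimated correlation, replicates at 2.72 and 1.59). On it 18 genes were higher and 13 lower, 4 passed over all genes and 5 over the list alone. Examples are Il2ra, for a chain of the IL-2 receptor, at least 501-fold higher, Tnfsf11, which encodes RANKL, at least 423-fold higher (adjusted p = 0.0258 for both) and Tmem176b, higher by 5.17 (adjusted p = 0.0365). The 5th, named after its values were seen, is the stem cell factor receptor gene Kit, higher by 5.36. The gut homing and tissue retention list shifted up by 3.01 (adjusted p = 6.64e-06, adjusted p = 0.0694 with an estimated correlation, replicates at 3.66 and 2.49). Among its 19 genes 14 were higher, 2 passed over all genes (Cxcr6 and Litaf) and 3 over the list alone, the additional one being the ATP receptor gene P2rx7 (5.16; list-alone adjusted p = 0.00695), and Itga4 was lower by 1.94 without passing.

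The immediate early and stress response list shifted up by 2.32 (adjusted p = 6.73e-13, adjusted p = 0.102 with an estimated correlation, replicates at 2.28 and 2.43). Of 30 genes, 28 were higher. None passed over all genes and 2 passed over the list alone: the stress gene Gadd45b (6.10 ± 0.19 against 0.17 ± 1.60; 0.00368) and the transcription factor gene Atf3 (higher by 5.82; 0.0118), while the chaperone gene Hspa1a (4.93) and Nfkbiz (2.93) did not. Cytotoxic effectors (17 genes, 11 higher) shifted up by 1.35 (adjusted p = 0.0119, adjusted p = 0.211 with an estimated correlation, replicates at 1.35 and 1.46), with 0 passing over all genes by limma and 1 over the list alone, the granzyme gene Gzmc (7.65; 0.0236), whereas Cst7 was lower by 2.52 without passing. The type 1 programme (23 genes, 17 higher) shifted up by 1.07 (adjusted p = 0.00671, adjusted p = 0.413 with an estimated correlation), by 0.24 in replicate 1 and 1.82 in replicate 2. The list lay at the 95.2nd percentile of random lists of matched expression, within their central 95%. None of its genes passed either way, among them Bhlhe40 (higher by 3.62), the interferon-γ gene Ifng (2.05), Fasl (lower by 4.0; also on the cytotoxic list) and Tbx21, which encodes T-bet (higher by 1.52, with 1 spleen value).

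NK maturation and circulation genes shifted down by 1.68 (adjusted p = 0.00698, adjusted p = 0.413 with an estimated correlation, replicates at -2.28 and -1.17). Of 22 genes, 16 were lower, 1 passed over all genes and 3 over the list alone. These were S1pr5, the protease gene Cma1 (lower by 5.33; 0.00262; shared with the mast cell list) and the L-selectin gene Sell (at least 93.4-fold lower, 0.0395, with signal on 1 of 2 gut arrays), and the egress receptor gene S1pr1, at least 34.2-fold lower, did not pass. B and plasma cell markers moved the same way, by -0.87 (adjusted p = 0.0393, adjusted p = 0.186 with an estimated correlation, replicates at -1.04 and -0.70). Of 17 genes, 15 were lower, such as Cd79a, at least 15.8-fold, and Cd19 (-1.64), and 0 passed either way by limma. NK cell receptors, with a mean difference of -0.33, a median of -0.71 and a test statistic of opposite sign, were not called (shift -0.02, adjusted p = 0.589), though Lilrb4a (5.67) and Klrb1b (4.31) rose when adjusted over the list alone, as did the T cell marker Ctla4 (7.05; 0.00711) on a list that was not called (0.47).

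Some calls depended on the processing or on 1 array: B and plasma markers were lost with quantile normalisation (-0.83), no filter (-0.70), the mean of probes (-0.68), the replicate block (-0.84) or marked spots kept (-0.83) and without any single array (-0.79 and -0.94 without SI replicate 1 and 2, -0.77 and -1.0 without spleen replicate 1 and 2), and NK maturation was lost without spleen replicate 1 (-0.83) or SI replicate 2 (-1.34) and reached -2.61 without spleen replicate 2. Quantile normalisation and the authors' values ended the calls of cytotoxic effectors (0.85 and 0.79) and the type 1 programme (0.53 and 0.56), as did leaving out SI replicate 1 (0.90 and 0.99) or spleen replicate 2 (0.93 and 0.17), the type 1 shift was 1.90 without spleen replicate 1, the immediate early shift was 1.54 with quantile normalisation and the lymphoid tissue inducer shift 1.39 without SI replicate 1, and the 43 calls became 0 with only 4 arrays or without SI replicate 1, SI replicate 2 or spleen replicate 1, and 179 (93 higher and 86 lower) without spleen replicate 2.

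What separates SI NKp46+GFPhigh cells from SI NKp46+GFP- cells, the populations with the highest and lowest mean Rorc among NKp46+ gut cells? NK cell receptors, cytotoxic effectors, the type 1 programme and NK maturation genes were lower in the GFPhigh cells relative to all genes (shifts of -1.16 to -2.54), while the lymphoid tissue inducer (shift 0.11), IL-17 and IL-22 (-0.30) and gut homing lists (-0.10) were not called. With an estimated correlation none of the 4 calls held (adjusted p = 0.159 for the NK receptor and cytotoxic lists, 0.608 for type 1 and 0.616 for NK maturation genes). The perforin gene Prf1 was lower by 5.24 and Eomes, for a transcription factor of NK cells, by 5.09, and Rorc was higher by 2.48 (adjusted p = 0.942). No single gene passed over all genes by limma (smallest adjusted p 0.088). At an unadjusted p under 0.05 there were 1206 genes, little above the 1107 that chance gives. The median gene was higher by 0.14 in GFPhigh cells.

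Of the genes with the smallest p, none of which passed, Selenop was at least 141-fold higher, Arpp19 at least 82.4-fold and Cdkn2aipnl at least 59.9-fold higher in GFPhigh cells (adjusted p 0.088, 0.088 and 0.0899). Lower were the inhibitory receptor gene Klra1 (at least 634-fold, adjusted p = 0.088), Wdr53 (at least 43.0-fold, adjusted p = 0.114) and Prf1 (adjusted p = 0.114), each with both arrays of a group beyond both of the other. Arpp19, Klra1 and Wdr53 had signal on 1 of 2 arrays of the lower group.

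NK cell receptors shifted by -2.54 (adjusted p = 9.96e-14, adjusted p = 0.159 with an estimated correlation, replicates at -2.64 and -2.44). Of 33 genes, 28 were lower, 0 passed over all genes by limma and 10 over the list alone. Examples are Klra1, Klra6 and Klra9 (both lower by 6.52) and Klra7 (at least 332-fold lower), Ly49 receptor genes open to cross-hybridisation within their family. Cytotoxic effectors shifted by -2.37 (adjusted p = 2.35e-06, adjusted p = 0.159 with an estimated correlation, replicates at -2.50 and -2.24). Of 17 genes, 16 were lower and 4 passed over the list alone: Prf1 (0.00155), the granzyme gene Gzma (at least 679-fold lower, open to cross-hybridisation), Cst7 (-3.21) and Tnfsf10, which encodes TRAIL (at least 24.6-fold lower).

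The type 1 programme shifted by -2.01 (adjusted p = 1.53e-05, adjusted p = 0.608 with an estimated correlation, replicates at -2.19 and -1.83). Of 23 genes, 18 were lower and 6 passed over the list alone. Among the 6 were Eomes (0.00634), the chemokine genes Ccl4 (-6.58) and Ccl5 (-3.48) and the receptor gene Ccr5 (at least 353-fold lower). NK maturation genes shifted by -1.16 (adjusted p = 0.0016, adjusted p = 0.616 with an estimated correlation, replicates at -1.06 and -1.27). Of 22 genes, 19 were lower and 1 passed over the list alone, the costimulatory receptor gene Cd27 (-4.75; 0.0491). Immediate early genes shifted by -0.65 (adjusted p = 0.0483, adjusted p = 0.616 with an estimated correlation, replicates at -0.85 and -0.45), 21 of 30 lower and 0 passing by limma, and the list means of the arrays overlapped. The call for immediate early genes was lost with quantile normalisation (-0.16), the authors' values (-0.24) or the mean of probes (-0.60) and without GFP- replicate 1 (-0.22), GFPhigh replicate 1 (-0.88) or GFPhigh replicate 2 (-0.42), and the shift was -1.08 without GFP- replicate 2. NK maturation was lost without GFP- replicate 1 (-0.83) or GFPhigh replicate 2 (-0.72) and shifted by -0.69 in the authors' values.

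**Figure D2:**
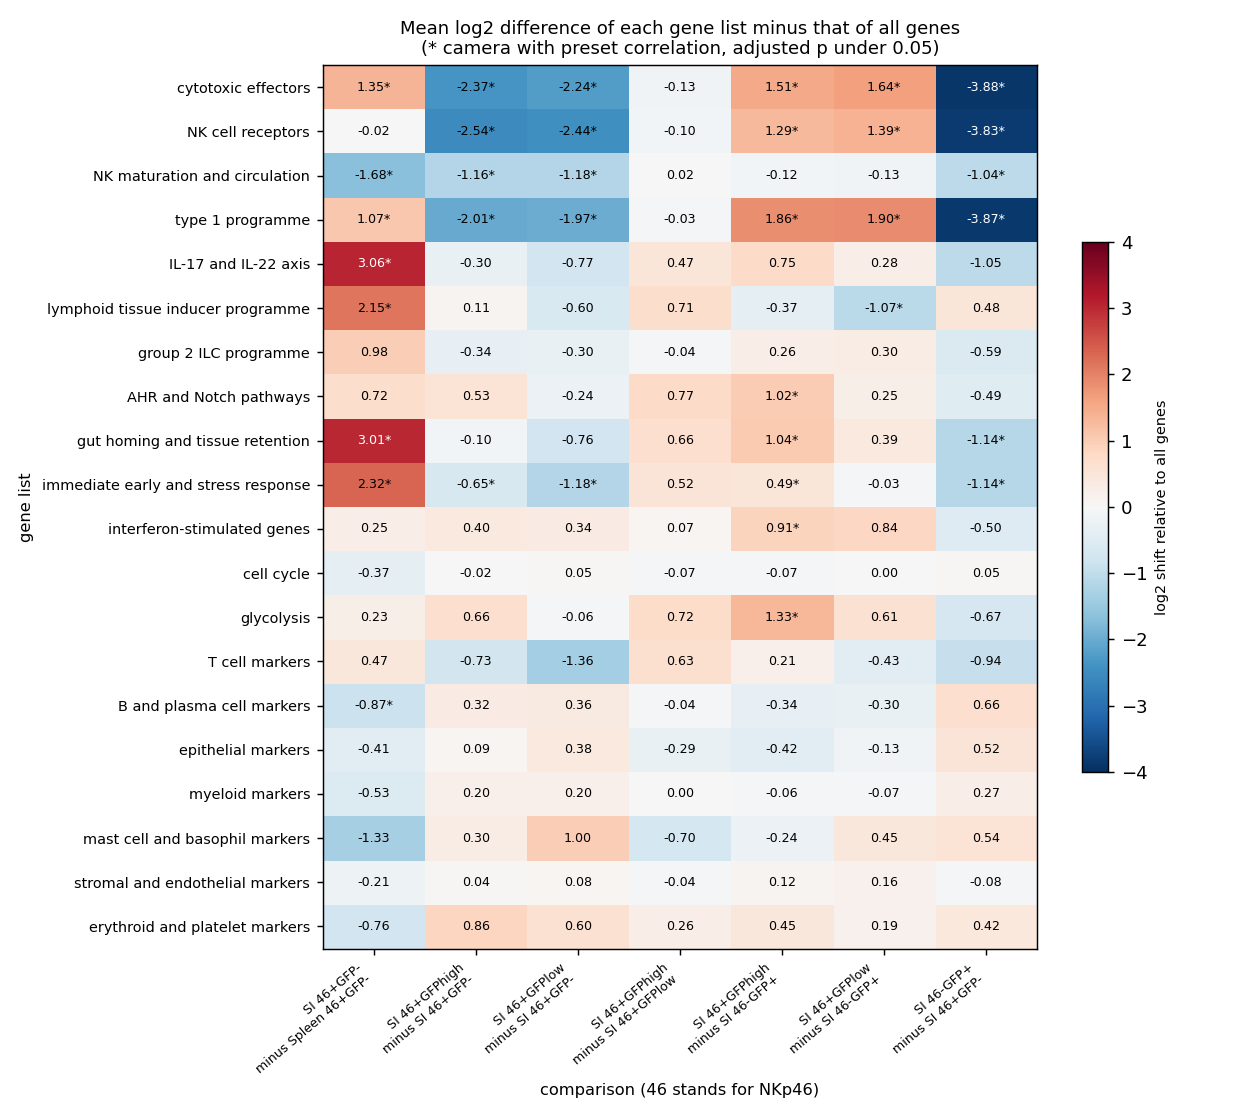
Shift in log2 units (colour) of each of 20 gene lists (vertical axis) in each of 7 comparisons (horizontal axis); a star marks an adjusted p under 0.05 at the preset correlation. The NK cell receptor list ran from -3.83 in SI NKp46-GFP+ against SI NKp46+GFP- cells to 1.39 in SI NKp46+GFPlow against SI NKp46-GFP+ cells.

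How do SI NKp46+GFPlow cells, with intermediate mean Rorc, compare with SI NKp46+GFP- cells? NK cell receptors (-2.44), cytotoxic effectors (-2.24), the type 1 programme (-1.97), immediate early genes (-1.18) and NK maturation genes (-1.18) were lower in the GFPlow cells. With an estimated correlation no call held (adjusted p = 0.213, 0.213, 0.407, 0.407 and 0.533). The perforin gene Prf1 (1.42 ± 0.18 against 3.41 ± 0.49) and Eomes (-0.51 ± 0.06 against 2.03 ± 1.35) were lower by 1.99 and 2.54 without passing. Ncr1 and Rorc stood at 3.40 and 2.09 in GFPlow cells, and the median gene was higher by 0.36. Rorc was higher by 1.17 without passing by limma (adjusted p = 0.771), with differences of -0.005 in replicate 1 and 2.34 in replicate 2.

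By limma 6 genes were called, 5 higher and 1 lower in GFPlow cells, and 1961 had an unadjusted p under 0.05. Those higher with a symbol were F8, the clotting factor VIII gene, at least 18.4-fold, and 6330415B21Rik, at least 45.7-fold (adjusted p = 0.0399 for both), and the other 4 were transcripts without a gene symbol in the reference table. Lower with the smallest p, though not passed, were Klra1 (at least 685-fold with signal on 1 of 2 GFPlow arrays, adjusted p = 0.0665), Wdr53 (at least 62.2-fold; adjusted p = 0.0665) and the lymphocyte gene Ms4a4b (-5.98; adjusted p = 0.133).

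NK cell receptors (adjusted p = 6.62e-13, adjusted p = 0.213 with an estimated correlation, replicates at -2.19 and -2.69) had 27 of 33 genes lower, 0 passing over all genes and 7 over the list alone. These include Klra1, Klre1 (-4.82; 0.00868), Klra10 (-7.48) and Klra7 (-6.73), open to cross-hybridisation. Cytotoxic effectors (adjusted p = 1.74e-05, adjusted p = 0.213 with an estimated correlation, replicates at -2.38 and -2.10) had 14 of 17 genes lower, 3 of them passing over the list alone: Gzma (at least 256-fold with signal on 1 of 2 GFPlow arrays, 0.0348, open to cross-hybridisation), Cst7 (-2.97) and Tnfsf10 (at least 28.3-fold lower; 0.0427 for both). In the type 1 programme (adjusted p = 7.07e-06, adjusted p = 0.407 with an estimated correlation, replicates at -1.52 and -2.42) 19 of 23 genes were lower and 1 passed over the list alone, the chemokine gene Ccl4 (-5.91; 0.0331), while Ccl5 (-3.74) did not.

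Immediate early genes (adjusted p = 2.37e-05, adjusted p = 0.407 with an estimated correlation, replicates at -1.39 and -0.96) had 24 of 30 genes lower, with the phosphatase gene Dusp2 alone passing over the list (-5.64; 0.0288). NK maturation genes (adjusted p = 0.00328, adjusted p = 0.533 with an estimated correlation, replicates at -1.51 and -0.85) had 16 of 22 genes lower, and 3 passed over the list alone: Cd27 (-4.87; 0.0429) and the transcription factor gene Irf8 (-3.21; 0.0445) fell, and S1pr5 rose by at least 1.43-fold (0.0445). The IL-17 and IL-22 (-0.77), lymphoid tissue inducer (-0.60) and gut homing (-0.76) lists were not called, nor were T cell markers (shift -1.36, mean -1.08, median 0.10, adjusted p = 0.209) or mast cell and basophil markers, of which Fcer1a rose by 2.77 over its list alone (0.0342). The 6 gene calls became 0 with normexp, quantile normalisation, the authors' values, no filter, the replicate block, only 4 arrays or any 1 array of the 2 groups left out. Immediate early genes lost the call with quantile normalisation (-0.43) and the authors' values (-0.54) and shifted by -0.75 without GFP- replicate 1, and NK maturation lost it without GFP- replicate 1 (-0.84).

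Do SI NKp46+GFPhigh and SI NKp46+GFPlow cells, which differ in the level of the reporter, differ in these groups? No list was called between them, though normexp and the replicate block each called 1 and the mean of probes 2, and the NK cell lists stood close to 0: NK cell receptors at -0.10, cytotoxic effectors at -0.13, the type 1 programme at -0.03 and NK maturation at 0.02. For the NK receptor, cytotoxic and type 1 lists the median difference was positive (0.06, 0.30 and 0.31) where the mean was negative (-0.22, -0.25 and -0.15). The largest shifts were those of AHR and Notch pathways (0.77), glycolysis (0.72), the lymphoid tissue inducer programme (0.71; adjusted p = 0.179), mast cell and basophil markers (-0.70), gut homing (0.66) and T cell markers (0.63), and the IL-17 and IL-22 axis stood at 0.47. Immediate early genes had the smallest adjusted p (shift 0.52, adjusted p = 0.0654; 0.818 with an estimated correlation). Of 30 genes, 25 were higher. Prf1 was lower in GFPhigh cells by 3.25 (adjusted p = 0.481 over all genes; 0.0288 over its list alone). Eomes (lower by 2.54), Il23r (higher by 1.78) and Rorc (higher by 1.31) did not pass, and the median gene was lower by 0.18.

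By limma 5 genes were called, and 1092 had an unadjusted p under 0.05, no more than the 1107 that chance gives. F8 fell by at least 18.7-fold and 6330415B21Rik by at least 46.6-fold in GFPhigh cells (adjusted p = 0.0342 for both), with signal on both GFPlow arrays and on no array of the GFPhigh cells, and the other 3 were transcripts without a symbol, 1 higher and 2 lower. Higher without passing were Tcf7l1, a transcription factor gene of the Wnt pathway (at least 19.1-fold; adjusted p = 0.131, but -0.78 with normexp), Arpp19 (5.14) and Paxbp1 (at least 49.5-fold; adjusted p = 0.202 for both). These 5 calls became 0 with normexp, quantile normalisation, the authors' values, the replicate block, only 4 arrays or any 1 array of the 2 groups left out.

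What distinguishes SI NKp46+GFPhigh cells from SI NKp46-GFP+ cells, which match them in Rorc (3.40 and 3.03)? Type 1, NK receptor and cytotoxic genes were higher in the NKp46+ cells relative to all genes (shifts of 1.86, 1.29 and 1.51). With an estimated correlation none of these calls held (adjusted p = 0.215 for each). Ccr7, whose receptor directs cells to lymph nodes, was lower by 5.63. The T-bet gene Tbx21 was higher by 2.63 and the interferon-γ gene Ifng by 4.98. The lymphoid tissue inducer list as a whole (shift -0.37, adjusted p = 0.772) was not called. The glycolysis, AHR and Notch, gut homing, interferon-stimulated and immediate early lists were also called higher, each only at the preset correlation. Ncr1 was higher by 4.72 (adjusted p = 0.288), and the median gene was lower by 0.13.

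By limma 0 genes passed over all genes (smallest adjusted p 0.0731). At an unadjusted p under 0.05 there were 1103 genes, no more than the 1107 that chance gives. Higher with the smallest p, without passing, were Cdkn2aipnl (at least 72.9-fold), Tcf7l1 (at least 19.8-fold) and Arpp19 (5.37; adjusted p 0.0731, 0.117 and 0.117). Lower were Parp12 (at least 10.1-fold), Wdr53 (at least 103-fold with signal on 1 of 2 GFPhigh arrays; adjusted p = 0.0731 for both) and Ccr7 (adjusted p = 0.0781), the last passing over the lymphoid tissue inducer list alone (0.000875), on which the B follicle homing receptor gene Cxcr5 (-6.59; 0.0611) did not.

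The type 1 programme (adjusted p = 2.32e-06, adjusted p = 0.215 with an estimated correlation, replicates at 1.46 and 2.27) had 20 of 23 genes higher and 3 passing over the list alone: Ifng (0.0176), the chemokine gene Xcl1 (6.36; 0.0176) and Tbx21 (0.042). NK cell receptors (adjusted p = 0.000114, adjusted p = 0.215 with an estimated correlation, replicates at 1.71 and 0.94) had 20 of 33 genes higher and 1 passing, the inhibitory receptor gene Lilrb4a (4.25; 0.0269), while Slamf7 (3.87) did not. Cytotoxic effectors (adjusted p = 0.00379, adjusted p = 0.215 with an estimated correlation, replicates at 1.54 and 1.48) had 12 of 17 genes higher and 2 passing, the granule gene Nkg7 (5.32) and the cathepsin gene Ctsw (5.76; 0.0418 for both), while the lysosomal gene Lamp1 was lower by 3.46.

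Glycolysis genes shifted by 1.33 (adjusted p = 0.0071, adjusted p = 0.215 with an estimated correlation, replicates at 0.89 and 1.69). Of 18 genes, 15 were higher, such as Gpi1 (2.81) and Pfkl (4.20), and 0 passing by limma. The AHR and Notch list shifted by 1.02 (adjusted p = 0.0231, adjusted p = 0.215 with an estimated correlation, replicates at 1.05 and 0.99). Of 13 genes, 10 were higher and 0 passed, the aryl hydrocarbon receptor gene Ahr by 2.06. Gut homing genes shifted by 1.04 (adjusted p = 0.0469, adjusted p = 0.215 with an estimated correlation, replicates at 1.1 and 0.99). Of 19 genes, 13 were higher and 0 passed: Cxcr6 was higher by 2.27 and the neuropeptide receptor gene Vipr2 at least 34.3-fold lower, with signal on 1 of 2 GFPhigh arrays. Interferon-stimulated genes shifted by 0.91 (adjusted p = 0.0469, adjusted p = 0.215 with an estimated correlation, replicates at 0.94 and 0.87). Of 26 genes, 16 were higher and 1 passed, Irf7 (5.14; 0.0388). Immediate early genes shifted by 0.49 (adjusted p = 0.00696, adjusted p = 0.434 with an estimated correlation, replicates at 0.48 and 0.49). Of 30 genes, 25 were higher and 0 passed, at the 47.2nd percentile of random lists of matched expression. Epithelial markers were at -0.42 (adjusted p = 0.0552).

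Quantile normalisation, the authors' values and leaving out GFPhigh replicate 1 or NKp46- replicate 2 ended the calls of the AHR and Notch (1.04, 0.89, 0.87, 0.90), gut homing (0.78, 0.68, 0.62, 0.68), interferon-stimulated (0.83, 0.68, 0.65, 0.69) and immediate early lists (0.01, 0.03, 0.26, 0.25), leaving out GFPhigh replicate 2 those of gut homing (1.46), interferon-stimulated genes (1.16) and glycolysis (1.27), and leaving out NKp46- replicate 2 those of cytotoxic effectors (1.22) and glycolysis (0.98). Glycolysis was also lost with quantile normalisation (0.93), gut homing, AHR and Notch and interferon-stimulated genes with no filter (0.86, 0.75, 0.73), gut homing and interferon-stimulated genes with normexp (0.73, 0.51), where AHR and Notch stood at 0.65, and interferon-stimulated genes with the mean of probes (0.81) or only 4 arrays (adjusted p = 0.082).

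How do SI NKp46+GFPlow cells compare with SI NKp46-GFP+ cells? Type 1, cytotoxic and NK receptor genes were higher in the NKp46+ GFPlow cells (shifts of 1.90, 1.64 and 1.39), and lymphoid tissue inducer genes were lower (-1.07). With an estimated correlation the 4 calls were lost (adjusted p = 0.428, 0.427, 0.427 and 0.428). Ifng was higher by 6.33 and Prf1 by 3.36, and Ccr7 lower by 5.24. Gut homing genes as a list (0.39) were not called. Ncr1 was at 3.40 against -0.45, Rorc at 2.09 against 3.03, and the median gene was higher by 0.06.

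By limma 8 genes were called, 5 higher and 3 lower. At an unadjusted p under 0.05 there were 1042 genes, no more than the 1107 that chance gives. F8 rose at least 22.4-fold and 6330415B21Rik at least 55.6-fold, while Wdr53 fell at least 150-fold and Parp12, of the ADP-ribosyltransferase family, at least 11.6-fold (adjusted p = 0.035 for all). The other 4 were transcripts without a gene symbol in the reference.

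The type 1 programme (adjusted p = 1.09e-05, adjusted p = 0.428 with an estimated correlation, replicates at 2.12 and 1.67) had 21 of 23 genes higher, 2 of them passing over the list alone, Ifng (0.00507) and Xcl1 (5.93; 0.026). Cytotoxic effectors (adjusted p = 0.000417, adjusted p = 0.427 with an estimated correlation, replicates at 1.66 and 1.62) had 14 of 17 genes higher and 2 passing, Prf1 (0.0237) and Ctsw (5.79; 0.0409). NK cell receptors (adjusted p = 1.09e-05, adjusted p = 0.427 with an estimated correlation, replicates at 2.14 and 0.69) had 25 of 33 genes higher and 0 passing by limma either way, such as Lilrb4a (3.20) and Klri2 (5.16). Lymphoid tissue inducer genes shifted by -1.07 (adjusted p = 0.0113, adjusted p = 0.428 with an estimated correlation, replicates at -1.27 and -0.88). Of 31 genes, 24 were lower and 1 passed over the list alone, Ccr7 (0.0014), while the OX40 ligand gene Tnfsf4 (at least 8.62-fold lower; 0.0505) did not. Vipr2 fell at least 206-fold when adjusted over the gut homing list alone (0.0159). Without GFPlow replicate 1 the calls of NK cell receptors (0.76) and cytotoxic effectors (1.33) were lost, and without NKp46- replicate 1 or GFPlow replicate 2 that of lymphoid tissue inducer genes (-0.79 and -0.98). The 8 gene calls became 0 with normexp, quantile normalisation, the authors' values, the replicate block, only 4 arrays or any 1 array of the 2 groups left out.

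What separates SI NKp46-GFP+ cells from SI NKp46+GFP- cells, which differ in both sort markers? NK cell receptors, cytotoxic effectors and type 1 genes were lower in the NKp46- cells (shifts of -3.83, -3.88 and -3.87), the largest list shifts between gut populations. The first 2 calls held with an estimated correlation (adjusted p = 0.0468 for both) and that of type 1 genes did not (adjusted p = 0.112). Ifng was lower by 8.16 and Prf1 by 5.35. Ccr7 (5.19), Cxcr5 (at least 156-fold) and Tnfsf4 (at least 7.35-fold) were higher, while the lymphoid tissue inducer list as a whole (shift 0.48, adjusted p = 0.478) was not called. Ncr1 was lower by 5.68 (adjusted p = 0.142) and Rorc higher by 2.11, and the median gene was higher by 0.34.

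By limma 0 genes passed over all genes, and 1930 had an unadjusted p under 0.05 (smallest adjusted p 0.062). Higher with the smallest p, without passing, were Abhd6 (at least 75.3-fold; adjusted p = 0.062), Parp12 (at least 9.90-fold; adjusted p = 0.074) and 1700028K03Rik (at least 37.6-fold with signal on 1 of 2 GFP- arrays; adjusted p = 0.0792). Lower were Klra1 (-9.37), Ifng (adjusted p = 0.0792 for both) and Ms4a4b (-6.57; adjusted p = 0.0857), each with both arrays beyond both of the other group.

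NK cell receptors (adjusted p = 5.99e-24, adjusted p = 0.0468 with an estimated correlation, replicates at -4.31 and -3.38) had 32 of 33 genes lower and 18 passing over the list alone, such as Klra1, Lilrb4a (-6.05), Klre1 (-4.79) and the NKG2A gene Klrc1 (-3.52). Cytotoxic effectors (adjusted p = 1.38e-11, adjusted p = 0.0468 with an estimated correlation, replicates at -4.04 and -3.72) had 15 of 17 genes lower, and over the list alone 10 fell and 1 rose. Examples are Prf1 (0.00135), Nkg7 (-6.78), Gzma (at least 601-fold lower, with signal on 1 of 2 NKp46- arrays) and Gzmb (-6.31), the last 2 open to cross-hybridisation. The gene that rose, named after its values were seen, is Lamp1 (3.03). The type 1 programme (adjusted p = 5.4e-14, adjusted p = 0.112 with an estimated correlation, replicates at -3.65 and -4.10) had 19 of 23 genes lower and 10 passing over the list alone, among them Ifng, Ccl4 (at least 343-fold with signal on 1 of 2 NKp46- arrays), Xcl1 (-7.56) and Ccr5 (at least 422-fold).

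Immediate early genes shifted by -1.14 (adjusted p = 1.95e-05, adjusted p = 0.296 with an estimated correlation, replicates at -1.33 and -0.95). Of 30 genes, 23 were lower and 1 passed over the list alone, Dusp2 (-6.47; 0.0126). The list lay at the 7.37th percentile of random lists of matched expression, within their central 95%. NK maturation genes shifted by -1.04 (adjusted p = 0.00294, adjusted p = 0.351 with an estimated correlation, replicates at -1.22 and -0.87). Of 22 genes, 15 were lower, and over the list alone Cd27 fell (-4.62; 0.0285) and Ccr7, shared with the lymphoid tissue inducer list, rose (0.00107). Gut homing genes shifted by -1.14 (adjusted p = 0.0324, adjusted p = 0.296 with an estimated correlation, replicates at -1.55 and -0.74). Of 19 genes, 14 were lower and the list means of the arrays overlapped. The 2 genes passing over the list alone rose: Vipr2 (at least 176-fold) and the receptor activity modifier gene Ramp1 (3.59; 0.0102 for both). Over the lymphoid tissue inducer list alone Ccr7 (0.0015), Cxcr5 (0.0143) and Tnfsf4 (0.0283) rose. B and plasma cell markers were at 0.66 (adjusted p = 0.132) and epithelial markers at 0.52 (adjusted p = 0.0686). The gut homing call was lost with normexp (-0.83), quantile normalisation (-0.64), the authors' values (-0.54) or no filter (-0.98) and without GFP- replicate 1 (-0.38) or NKp46- replicate 2 (-0.78), with -1.91 without GFP- replicate 2, and the NK maturation call without GFP- replicate 1 (-0.71) or NKp46- replicate 2 (-0.88), with -0.68 in the authors' values. Immediate early genes lost the call with quantile normalisation (-0.17) and the authors' values (-0.27), with -0.71 without GFP- replicate 1, and the count of genes was 4 with quantile normalisation or marked spots kept.

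Markers of other cells and the remaining programmes were called in few or no comparisons. T cell markers ranged from -1.36 to 0.63 (smallest adjusted p 0.209), myeloid markers from -0.53 to 0.27 (0.135), mast cell and basophil markers from -1.33 to 1.00 (0.0632), epithelial markers from -0.42 to 0.52 (0.0552), stromal and endothelial markers from -0.21 to 0.16 (0.589) and erythroid and platelet markers from -0.76 to 0.86 (0.235). Cell cycle genes (-0.37 to 0.05; 0.377) and the group 2 ILC programme (-0.59 to 0.98; 0.138) were not called in any comparison. The median, mean and test of a list differed in sign only where the list was not called. Glycolysis, AHR and Notch, and interferon-stimulated genes were called only between SI NKp46+GFPhigh and SI NKp46-GFP+ cells. List members passing over all genes were found only in the comparison of gut with spleen cells, where Rora, Cxcr6, Litaf, Il2ra, Tnfsf11, Tmem176b and S1pr5 passed.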

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

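The data were fitted again with normexp background correction, quantile normalisation, the authors' values, no filter on background, the mean of all probes, the replicate block, the slide as a random block, only the 4 arrays of a comparison and each array left out, all chosen beforehand, and with the outlier-marked spots kept, added after the results were seen. Of 42 list calls, 39 held with normexp, 30 with quantile normalisation, 32 with the authors' values, 37 with no filter, 39 with the mean of probes, 41 with the replicate block, 42 with the slide block and 41 with marked spots kept. None changed direction. With only 4 arrays 35 of 36 held, and with 1 array left out 167 of 204. Immediate early and stress calls made up 4 of the 12 lost with quantile normalisation and 4 of the 10 lost with the authors' values.

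Called genes in SI NKp46+GFP- against Spleen NKp46+GFP- cells went from 43 to 0 with only 4 arrays, and from 0 to 179 with 1 array left out. In SI NKp46+GFPlow against SI NKp46+GFP- cells the 6 calls became 0 with normexp, quantile normalisation, the authors' values, no filter, the replicate block and only 4 arrays, and were 0 with any array left out. In SI NKp46+GFPhigh against SI NKp46+GFPlow cells the 5 calls, and in SI NKp46+GFPlow against SI NKp46-GFP+ cells the 8 calls, became 0 with normexp, quantile normalisation, the authors' values, the replicate block and only 4 arrays, and were 0 with any array left out. Between SI NKp46-GFP+ and SI NKp46+GFP- cells 4 genes were called with quantile normalisation and 4 with marked spots kept, against 0. For the mean of the 4 SI groups against spleen, 102 calls became 159 with quantile normalisation, 155 with the authors' values and 67 with the replicate block, and ranged from 18 to 259 with 1 array left out. Of the 43 calls in SI NKp46+GFP- against Spleen NKp46+GFP- cells, 20 were also called with normexp, 26 with the authors' values and 28 with the replicate block. With no filter 30 were also called, with the mean of probes 33, with quantile normalisation 37, with marked spots kept 41 and with the slide block 43. With only 4 arrays there are fewer samples, and a block takes up degrees of freedom. The cause of the other moves, among them the rises without an array, was not tested.

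Called lists in SI NKp46+GFP- against Spleen NKp46+GFP- cells were 8 and became 5 with quantile normalisation and 5 to 7 with 1 array left out. In SI NKp46+GFPhigh against SI NKp46+GFP- cells the 5 ranged from 3 to 5, and in SI NKp46+GFPlow against SI NKp46+GFP- cells the 5 ranged from 4 to 8. Between SI NKp46+GFPhigh and SI NKp46+GFPlow cells, where 0 were called, normexp called 1, the mean of probes 2, the replicate block 1, and leaving out an array 0 to 2. For SI NKp46+GFPhigh against SI NKp46-GFP+ cells the 8 became 3 with quantile normalisation, 4 with the authors' values and 2 to 10 with 1 array left out. The 4 lists of SI NKp46+GFPlow against SI NKp46-GFP+ cells ranged from 2 to 4, and the 6 of SI NKp46-GFP+ against SI NKp46+GFP- cells from 4 to 8. The cause of these moves was not tested.

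The mean correlation within groups was 0.753 with normexp and 0.790 with no filter, and that between groups 0.776 with no filter, which adds probes near background. Of 2312 values of single genes across settings, 2139 kept both sign and call status, 157 were weaker, 14 stronger and 0 reversed. Genes not called in either fit count among the 2139, and only genes called in the main fit could be weaker or reversed. These counts therefore do not measure how well gene calls held. The sign changed for 2 values that were not called. Tcf7l1 in SI NKp46+GFPhigh against SI NKp46+GFPlow cells went from 5.38 to -0.78 with normexp. Cd48 in SI NKp46+GFPhigh against SI NKp46+GFP- cells went from -4.52 to 0.22 with the authors' values, and the causes were not tested. The slide and the Feature Extraction version were not separated, because both coincide with the replicate number in the SI arrays. No slide held both SI and Spleen arrays, so differences of gut from spleen cannot be told apart from differences between slides. The slide block does not address this, because only SI arrays shared a slide. The choice of brightest probe was not varied beyond the mean of probes. Where a population has a single array after leaving one out, its lone array is assumed to vary like the other groups. Signal well above background means that a spot exceeds the local noise of its array. It does not limit the spread added by amplification from 1000 cells.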

Other observations

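The comparison of the mean of all 4 SI populations with Spleen NKp46+GFP- cells was chosen after the data had been seen, and so were the tests of handling, of splenic-type NK cells (the median shares and the level that their share needs) and of the Rorc share, while the tests of the mixture sum, the dynamic range and on-off detection were written before. How did the mean of the gut populations differ from spleen? It was higher in the RORγt-linked, tissue residence and immediate early lists and lower in NK maturation and NK receptors. All gut populations but SI NKp46+GFP- cells were sorted as GFP+, and SI NKp46-GFP+ cells as NKp46-. The comparison thus mixes tissue with the sort markers and with the slide. With an estimated correlation only the gut homing call held (adjusted p = 0.0491, against 0.111 to 0.123), and NK receptors were not lower in SI NKp46+GFP- cells alone (shift -0.02). Cxcr6 rose at least 449-fold (adjusted p = 0.00583), Rora by 6.74 (adjusted p = 0.00247) and Il22 at least 384-fold (adjusted p = 0.0136), with Cxcr6 and Il22 signal on 1 of 2 spleen arrays. S1pr5 fell at least 115-fold (adjusted p = 0.00225), with signal on 2 of 8 gut arrays, and the adaptor gene Sh2d1a, of SLAM receptor signalling, at least 110-fold (adjusted p = 0.0136), with signal on 7 of 8. By limma 102 genes were called, 68 higher and 34 lower, with 2118 at an unadjusted p under 0.05, and 69 of the 102 have a symbol. Without spleen replicate 1 the count was 18 (10 higher and 8 lower), and without spleen replicate 2 it was 259 (125 higher and 134 lower).

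Rorc was at least 105.5-fold higher, with signal on 1 of 2 spleen arrays, but as a gene behind the sort it is no finding. Named after their values were seen, further genes that rose are Il23r (at least 160-fold, with signal on 1 of 2 spleen arrays), Litaf (7.09), Dgat1 (6.79) and the checkpoint receptor gene Ctla4 (6.57). Others were the immediate early genes Atf3 (5.63) and Gadd45b (5.06), P2rx7 (5.47), the signalling gene Irak2 (5.35), Tmem176b (5.14) and the stress sensor gene Ern1 (4.61). Without signal in spleen, Tnfsf11 rose at least 520-fold, Il2ra at least 436-fold, Phlda1 at least 404-fold and Tnfrsf9, which encodes 4-1BB, at least 58.5-fold. Genes that fell include the transcription factor gene Spi1 (by 5.44), Cma1 (by 5.29) and Cst7 (by 4.90). Klra1 and Klra6, open to cross-hybridisation, were called lower in the mean, but in SI NKp46+GFP- cells they stood at 4.52 and 3.90, against 5.22 (1 array) and 5.49 in spleen and -5.20 to 0.87 in the other gut populations.

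NK maturation genes shifted by -2.52 and NK receptors by -2.22 (adjusted p = 1.13e-08 and 2.96e-08, adjusted p = 0.123 with an estimated correlation for both), with 20 of 22 and 29 of 33 genes lower. On the former list S1pr5, Cma1, Sell (at least 241-fold, with signal on 2 of 8 gut arrays), Cd27 (-4.46), Irf8 (-3.63) and the integrin gene Itgam (-4.29) fell when adjusted over the list alone. Immediate early genes (1.58; adjusted p = 1.13e-08, adjusted p = 0.123 with an estimated correlation) had 25 of 30 higher, lymphoid tissue inducer genes (2.15; 7.98e-08, adjusted p = 0.111 with an estimated correlation) 22 of 31, and the IL-17 and IL-22 axis (2.53; 9.3e-08, adjusted p = 0.111 with an estimated correlation) 15 of 17. The gut homing list (2.51; adjusted p = 1.51e-06) held with an estimated correlation (adjusted p = 0.0491), with 15 of 19 genes higher. Cytotoxic effectors (-0.77; adjusted p = 0.43) and the type 1 programme (-0.89; adjusted p = 0.296) were not called, though Eomes fell by 4.40 over its list alone (0.00476). In SI NKp46+GFP- cells Cd27 stood at 1.98 and Eomes at 2.03, against 2.88 and 3.70 in spleen and -2.77 and -3.06 in SI NKp46+GFPhigh cells. Irf8 and Itgam stood at 2.37 and -1.61 in SI NKp46+GFP- cells, against 4.24 and 1.84 in spleen. All 6 list calls held in every setting, with -1.68 for NK maturation without spleen replicate 1 and 1.05 for immediate early genes without spleen replicate 2.

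SI NKp46+GFP- cells carried Rora (5.79), Tnfsf11 (3.33), Il23r (2.81) and Il22 (2.79 ± 2.12) above spleen, although they were sorted as reporter-negative, at 0.965, 0.801, 0.351 and 0.344 of the way from spleen to SI NKp46+GFPhigh signal on the linear scale. If they were a mix of GFP+ cells and splenic-type NK cells, the share read from RORγt-linked genes (0.858, 19 genes) and that read from NK genes (0.429, 43 genes) would sum to 1. The sum was 1.29 (0.625 to 1.57), an interval that holds 1. RORγt-linked genes here are Rorc and members of the IL-17 and IL-22 and lymphoid tissue inducer lists. They were taken as higher in SI NKp46+GFPhigh than in spleen cells, whether or not they followed Rorc among gut cells. The intervals given here resample genes, not arrays, so they do not measure the spread between samples. Cells of the splenic type would bring all their abundant transcripts. Yet 2 of 13 maturation genes lay below the lower 95% bootstrap bound of the NK share (0.309). These were S1pr5 (share at most 0.00838) and Cma1 (0.0249), the latter also on the mast cell list. Adjusted p was 0.000208 and 0.00756 by a one-sided moderated t test against that bound. Both genes also lay below it when any 1 array of the 2 populations was left out, with the bound kept fixed. For these genes this argues against splenic-type cells at the NK share, but a smaller share is not excluded. Single NK genes scattered widely around that share: Slamf6 and Itga2 read 0.051, and 10 genes read above 1, from Ccl5 (1.01) to Il12rb2 (18.5). A mix gives no true share above 1, but the spread of 2 arrays can lift a reading. Whether these genes exceed 1 beyond that spread was not tested. The median splenic share was also lower for the 13 maturation genes (0.058) than for 30 other NK genes (0.455), by -0.40 (permutation p = 0.0223, but 0.0233 to 0.144 without 1 array, so this difference alone decides nothing). GFP+ cells at the share that Rorc reads (0.177) would leave the other RORγt-linked genes lower than measured: their median excess was 1.72 (0.54 to 2.18, 15 of 18 above), but with the Rorc of the higher array (share 0.300) it was 1.37 (-0.04 to 1.59), so carried-over cells cannot be told apart from expression in the GFP- cells themselves, because Rorc differs too much between 2 arrays, and a gut population without RORγt that keeps part of its programme remains untested.

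Immediate early and stress genes were higher in SI NKp46+GFP- than in Spleen NKp46+GFP- cells at the preset correlation, but not with an estimated one. They were led by Gadd45b and Atf3, which passed over the list alone. A different dynamic range of the arrays would move any genes of like signal, but after quantile normalisation the mean difference of the list was 1.43 against -0.50 to 0.58 for matched random lists, which argues against it. Tissue handling that differs between gut and spleen would raise the genes in every gut population: the lowest shift, in SI NKp46+GFPlow cells, was 1.15 against a bound of 1.16, which is 50% of the shift in SI NKp46+GFP- cells, with 2.32, 1.67 and 1.18 in SI NKp46+GFP-, SI NKp46+GFPhigh and SI NKp46-GFP+ cells. With quantile normalisation the shifts were 1.54, 1.11, 1.38 and 1.37 in SI NKp46+GFP-, SI NKp46+GFPlow, SI NKp46+GFPhigh and SI NKp46-GFP+ cells. There the other gut populations lay closer to SI NKp46+GFP- cells, so the lowest shift sat at the bound (SE 0.39 over genes) only with the main scaling. Handling therefore cannot be told apart from a response in the gut, because all gut arrays shared 1 preparation. Per the labels splenocytes were freed with Collagenase VIII as well, so this enzyme alone does not set the gut arrays apart. Activation of the cells in the gut before isolation remains untested.

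F8, 6330415B21Rik and 2 more transcripts without a symbol were called in all 3 gut comparisons with SI NKp46+GFPlow cells, with signal on both GFPlow arrays. Chance on-off detection of transcripts amplified from few cells would give as many such probes to any 2 arrays of different groups. The GFPlow arrays held 65 probes seen on both and on no other array, against 6 to 318 over 40 mixed choices of 2 arrays, 8 of which had at least as many (median 31.5). Counted after that result was seen, among the 20 choices with different replicate numbers, as the GFPlow arrays have, the counts ran from 10 to 93 and 2 reached 65, both with spleen replicate 2. Chance detection is thus not excluded and could account for these calls, and a GFPlow-specific programme remains untested.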
